A study of Homo sapiens with 31 samples.

How the data were processed

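ZNF292 occupancy was measured by CUT&Tag in H9 human embryonic stem cells differentiated to ventrally patterned neuronal progenitors (D15) and immature cortical interneurons (D30), per the labels. The 31 libraries comprise 24 with the ZNF292 antibody, in 6 groups of 4 by day and line, and 7 with IgG. Groups and replicate numbers were taken from the sample titles, and per the labels the 4 replicates of a day come from independent differentiations. The growth and extraction protocols name the maintenance medium, the CUT&Tag kit and the purification, and the aligner, read filters and options of peak calling are not given in the sources used here.

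Per the submitters' processing notes, peaks were called with MACS2 on genome build hg38, without a stated version. Each deposited list belongs to 1 library, so replicates were not pooled. For each peak the deposited lists give the position, a score that equals 10 times the −log10 q-value rounded down, the fold (ratio) of the summit over local background, the −log10 p-value and the −log10 q-value. The lowest deposited −log10 q-value was between 2.00 and 2.10 in every list, as with a limit of q at 0.01. Scores, folds and p-values are the authors' and describe a peak within its own list. They were used only to rank, filter or describe peaks there, and libraries were compared by presence or absence of peaks. The peaks of the D30 library labelled ZNF-G1 IgG carry the name of a KRAB IgG library.

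The lists hold no read totals. For all peaks of all lists the fold and the −log10 p-value together fitted a whole number of fragments at the summit and a Poisson background, to within 0.002 in −log10 p, when the fold is the summit plus 1 over the background plus 1. The recovery found all 5000 simulated pairs. The lowest background in a list was taken as the genome background, which scales with depth. Backgrounds above it fell on multiples of 0.03 to within 0.002 in at least 61.3% of peaks of each list, where chance gives 13.3%. Such steps arise from reads extended to 300 bp and counted in a window of 10000 bp of the same library, so the values bear no trace of a control library in peak calling. For a genome of 2.7 Gb, an assumption, the background converts to reads. In D15 IgG replicates 2 to 4 under 1% of peaks lay at the lowest background, so their depth is an upper limit. A deeper library lets weaker sites pass the same limit, so peak numbers depend on depth as well as on binding.

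Peaks on chromosomes 1 to 22 and X were used, which left out 1182 peaks. Overlapping peaks of the 12 ZNF292 libraries of a day were merged with numpy, in place of the planned bedtools, and a library had a region when a peak overlapped it by 1 bp. Presence in 4 KRAB against 8 guide libraries was tested per region by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over regions whose total presence allows p under 0.05. The reference used here gives gene spans of GRCh38.p14 from RefSeq without strand or transcripts. The planned window around transcript starts was therefore replaced by a window of 1000 bp around both ends of each of 19974 protein-coding genes, called gene ends, 1 of which is the outermost transcription start. Genes that lie end to end or share an end share peaks. Gene ends were tested like regions. For 14 gene lists fixed before the data were examined, the percent of genes marked per library was compared by exact two-sided permutation of libraries, directly and after subtraction of the percent of all genes in the same library, with Benjamini-Hochberg adjustment over lists. All members were matched except 2 of the 14 pluripotency genes. Peak numbers were compared by exact two-sided permutation tests, whose smallest p is 0.00202 for 4 against 8 and 0.0286 for 4 against 4, and the difference of the guide effect between days by 100000 permutations of residuals. The smallest p of 4 against 4 leaves little room for an adjustment, so for single guides and for time, regions in 4 of 4 and 0 of 4 libraries were counted.

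The text names ZNF292 in every library, called genes of each list, and the 10 genes called with the lowest adjusted p per direction. Where none was called, the 10 genes with the largest difference in share are given as values, ties going to the highest median rank of the peak by −log10 p. The same rule gave 5 regions per day and direction, and uncalled list members are named as values. Some genes that the rule names are not reported here. In simulated presence tables of 20506 regions for D15 and 32540 for D30, with 20% of the regions changed, the region test called 79.5% and 80.4% of them, and 3.69% and 2.04% of its calls were unchanged regions. With 200 changed regions it called 0, since the smallest possible p then does not survive adjustment. In the data 1617 of 18491 regions tested were called lower at D15 and 1740 of 29314 at D30. These are smaller shares than the 20% changed in the simulation, so its rates do not carry over to them.

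Alternatives set before the data were examined were a −log10 q of at least 5, removal of peaks that overlap IgG peaks of the day, lists shortened to equal length by −log10 p, windows of 200 bp around summits, presence by a peak covering 50% of the region, gene windows of 500 and 2500 bp, no filter on total presence, testing within replicate numbers, and leaving out each library in turn. Added after seeing the data were whole gene spans, the D15 comparison without the libraries numbered 1, and thinning: summit fragments were drawn binomially at the ratio of the lowest background among the compared libraries to the library's own, and peaks with a −log10 p of at least 6 were kept. Thinning can remove peaks and cannot add any. It did not make the libraries even: the thinned peak number still fell with the background, with a Spearman correlation of -0.622 at D15 (n = 12, permutation p = 0.0349), -0.692 at D30 (n = 12, permutation p = 0.0151) and -0.905 in the 8 KRAB libraries (exact permutation p = 0.00456). Either thinning takes too much from deep libraries or these hold weaker signal over background, which the lists cannot separate, so thinned values do not decide on depth. For the overlap of the guides, a simulation chosen after seeing the data drew 20 sets of unchanged lines, with presence rates from a beta distribution fitted to regions in at least 2 of 4 KRAB libraries. The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.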

Results

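Genome-wide occupancy of ZNF292, a zinc finger protein, was profiled by CUT&Tag during the differentiation of H9 human embryonic stem cells toward cortical interneurons. CUT&Tag tethers a transposase to an antibody bound on chromatin, so that DNA near the antibody's target is tagged and sequenced. Cells were taken at day 15 (D15), as ventrally patterned neuronal progenitors, and at day 30 (D30), as immature cortical interneurons. The control line, KRAB, was set against ZNF-G1 and ZNF-G2, lines in which CRISPR interference (CRISPRi), a repressor guided to a chosen gene, was directed at ZNF292 with 2 different guides. The amount of ZNF292 protein or RNA was not analysed here. Each line had 4 libraries with the ZNF292 antibody at each day, from independent differentiations. Background was measured with a non-specific IgG antibody in 4 KRAB libraries at D15 and in 1 library labelled for each of the 3 lines at D30. Across the 31 libraries, 1075926 peaks were listed, of which 1074744 lay on chromosomes 1 to 22 and X.

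The ZNF292 libraries held between 21416 and 62406 peaks. Their depth, recovered from the lists as the number of fragments expected over a base of the genome, ranged from 0.0990 to 0.465 at D15 and from 0.120 to 1.04 at D30. At D15 the background averaged 0.231 ± 0.0647 (SD, n = 4) in KRAB and 0.205 ± 0.139 (SD, n = 8) in the guide libraries (exact permutation p = 0.741). At D30 it averaged 0.606 ± 0.235 (SD, n = 4) and 0.438 ± 0.282 (SD, n = 8, exact permutation p = 0.331). The D15 guide mean was raised by the libraries numbered 1, at 0.380 in ZNF-G1 and 0.465 in ZNF-G2. Every other D15 guide library except ZNF-G2 replicate 4 (0.184) had a lower background than the lowest KRAB library (0.173). No pair of ZNF292 libraries was a copy, since the most similar pair shared 38.6% of the regions found in either.

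**Figure D1:**
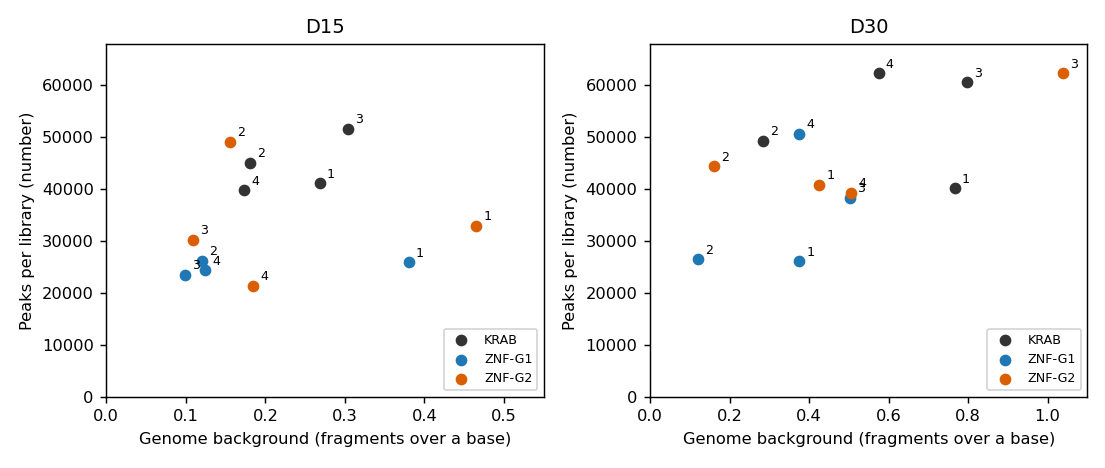
Number of peaks per library (vertical axis) against the recovered genome background in fragments over a base (horizontal axis) for the 12 ZNF292 libraries of D15 (left) and D30 (right), with the replicate number beside each point. At D15 the ZNF-G1 and ZNF-G2 libraries numbered 1 have the highest backgrounds, 0.380 and 0.465, and hold 25930 and 32975 peaks.

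The first question was how far the ZNF292 antibody exceeded the assay's own background in control progenitors. Control progenitors yielded 44437 ± 5341 peaks (SD, n = 4) with the ZNF292 antibody and 12818 ± 16085 (SD, n = 4) with IgG, a log2 ratio of IgG to ZNF292 of -1.79 (exact permutation p = 0.0286, the smallest that 4 against 4 can give; 0.0762 after adjustment over 8 peak-number comparisons). Without any 1 of the KRAB ZNF292 libraries the call ended (exact permutation p = 0.0571), and without IgG replicate 1 the log2 ratio was -3.20 (exact permutation p = 0.0286). The call also ended after thinning to 1 depth, a setting chosen after seeing the data (log2 ratio -1.26, exact permutation p = 0.0857). The recovered depth was 0.173 to 0.303 in the ZNF292 libraries and 0.525 in IgG replicate 1. In IgG replicates 2 to 4 it was at most 0.0327 to 0.0600, below every ZNF292 library. The number of IgG peaks was 36815 in replicate 1 and between 2659 and 6733 in the others. The few peaks of IgG replicates 2 to 4, and the overlap with IgG peaks, may thus reflect low depth as well as the antibody. ZNF292 peaks lay within 1000 bp of an end of 56.6% ± 5.06 (SD, n = 4) of 19974 protein-coding genes at D15 in KRAB, and IgG peaks at 25.9% of them in replicate 1 and at no more than 1.73% in replicates 2 to 4. At D30 the IgG libraries held 24077 peaks in KRAB, 23672 in the library labelled ZNF-G1 and 22761 in ZNF-G2. They marked 33.8%, 19.8% and 26.5% of gene ends, with 1 library each and no test. The peaks of the library labelled ZNF-G1 carry the name of a KRAB library, so its line is uncertain. Of the D15 KRAB peaks, 13.1% ± 0.960 (SD, n = 4) overlapped an IgG peak of that day, and of the D30 KRAB peaks 23.9% ± 3.64 (SD, n = 4).

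The targeted gene was examined first in the comparison of the lines. ZNF292 lies on chromosome 6 from 87155565 to 87265943 (hg38). A peak stood at its lower-coordinate end in 4 of 4 KRAB libraries at D15 and in 0 of 4 ZNF-G1 and 0 of 4 ZNF-G2 libraries. In KRAB replicate 3 this peak spanned 87154911 to 87156314, with a fold of 11.01 over background in the deposited list, the highest of the 4 (8.06 to 11.01). At D30 the peak was listed in 4 of 4 KRAB, 0 of 4 ZNF-G1 and 2 of 4 ZNF-G2 libraries. Those of ZNF-G2 stood in replicate 3, from 87155093 to 87156241, and replicate 4, from 87155073 to 87155489, with folds of 4.15 and 4.91. From the strongest peak down they stood at 82.9% and 87.6% of their lists, and the D30 KRAB peaks, with folds of 8.40 to 11.97, at 2.68% to 8.71% of theirs. IgG peaks were listed at the same end in 1 of 4 D15 libraries and in each of the 3 D30 libraries, so a peak there is not specific to the antibody. The D15 IgG peak had a fold of 9.39 and stood at 2.27% of its list. At D30 the IgG folds were 4.33 in KRAB, 6.79 in the library labelled ZNF-G1 and 8.63 in ZNF-G2. These peaks stood at 93.0%, 15.95% and 5.69% of their lists. The ZNF-G2 IgG peak thus ranked above both ZNF292-antibody peaks of that line. The Fisher's exact p at D15 was 0.00202, the smallest that 4 against 8 can give, and 0.132 after Benjamini-Hochberg adjustment over the 5605 genes tested. At D30 it was 0.0606.

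The second question was which sites bound in control progenitors at D15 were missing in the guide lines. Across all genes, the share with a peak at a gene end fell from 56.6% ± 5.06 (SD, n = 4) in KRAB to 42.5% ± 5.62 (SD, n = 8) in the guide libraries (exact permutation p = 0.00202). Genes of neuronal structure and synapse fell from 69.3% ± 8.60 (SD, n = 4) to 39.8% ± 9.01 (SD, n = 8; adjusted exact permutation p = 0.0141 over 14 lists). Among their 22 members, 16 had a lower share and 2 a higher share of guide libraries with a peak. GRIN2B, a glutamate receptor subunit, had a peak in 4 KRAB, 1 ZNF-G1 and 1 ZNF-G2 library, and ANK2, a scaffold of the axon, in 4, 0 and 3. CNTNAP2, an adhesion molecule of neurons, had a peak in all 12 libraries. Fixed alongside as markers of another cell type, glial genes fell from 18.3% ± 6.38 (SD, n = 4) to 4.17% ± 3.45 (SD, n = 8; adjusted exact permutation p = 0.0141). This group held 7 of 15 members with no peak in any library. S100B, a calcium-binding protein of astrocytes, had a peak in 4 of 4 KRAB libraries, 1 of 4 ZNF-G1 and 0 of 4 ZNF-G2 libraries. Housekeeping genes fell from 84.4% ± 9.24 (SD, n = 4) to 67.2% ± 6.07 (SD, n = 8, adjusted exact permutation p = 0.0283). These permutations ran across replicate numbers, and results for the lists within replicate numbers are not given here. Within replicate numbers the smallest possible exact permutation p is 0.0123, before any adjustment over lists.

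Measured against the fall over all genes in the same library, none of the 14 lists passed at D15. The list of neuronal structure and synapse lay -15.4 points from KRAB on that scale (exact permutation p = 0.0202, adjusted 0.120). Non-neural lineage genes lay 16.7 points above it (exact permutation p = 0.00606, adjusted 0.0848), since 20% ± 10.7 (SD, n = 8) of them had a peak in the guide libraries and 17.5% ± 11.9 (SD, n = 4) in KRAB. The subtraction is in points, so lists with a low share in KRAB, which have less room to fall, are raised by it. Glial genes, whose share fell from 18.3% to 4.17%, lay -0.00763 points from KRAB on this scale. Calls on it for lists of low share therefore do not show an effect particular to the list. Once every library of the day had been thinned to the depth of the shallowest, a setting chosen after seeing the data, the share over all genes was 39.2% in KRAB and 30.1% in the guide libraries (exact permutation p = 0.283). Under it the list of neuronal structure and synapse lay -18.1 points from KRAB relative to all genes (adjusted exact permutation p = 0.0283), and no list passed without that subtraction. In lists of equal length only non-neural lineage genes passed relative to all genes (16.7 points, adjusted exact permutation p = 0.0283), while neuronal structure and synapse did not (-16.5 points, adjusted 0.0707). At a stricter threshold both passed (19.5 points, adjusted exact permutation p = 0.0283, and -17.7 points, adjusted 0.0424). With a window of 2500 bp only glial genes did (-22.3 points, adjusted exact permutation p = 0.0283). With peaks that overlap IgG peaks removed, the unsubtracted calls ended for neuronal structure and synapse (48.9% and 26.1%, adjusted exact permutation p = 0.0707) and for housekeeping genes (52.1% and 49.5%, adjusted exact permutation p = 0.683). In lists of equal length they ended for glial genes (adjusted exact permutation p = 0.151) and housekeeping genes (adjusted exact permutation p = 0.0707), and at a stricter threshold for glial genes (adjusted exact permutation p = 0.0601). Calls were also gained, at a stricter threshold by neural progenitor genes (51.4% and 34.03%, adjusted exact permutation p = 0.0141), and with windows of 500 and 2500 bp by cortical interneuron genes (adjusted 0.0424 and 0.0377). Cortical interneuron genes gained one without ZNF-G2 replicate 2 (adjusted exact permutation p = 0.0212), neural progenitor and cell cycle genes without ZNF-G2 replicate 3 (0.0424 for each), and CTCF and cohesin genes without ZNF-G2 replicate 3 (0.0424) or 4 (0.0318). Over whole gene spans all 3 ended (adjusted exact permutation p = 0.0990 for each), as they did without the libraries numbered 1 (0.0556 for each), both settings chosen after seeing the data. The housekeeping call also ended without KRAB replicate 2 or 4 (adjusted exact permutation p = 0.0848 for each), KRAB replicate 3 (0.106), or ZNF-G1 replicate 3 or 4 (0.0566 for each).

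The ventral telencephalic patterning genes, which set up the region where cortical interneurons arise, had a peak at 53.8% ± 9.93 (SD, n = 4) of gene ends in KRAB and at 44.7% ± 8.21 (SD, n = 8) in the guide libraries (adjusted exact permutation p = 0.206). The oligodendrocyte and ventral progenitor factor OLIG1 had a peak in all 12 libraries. Cortical interneuron genes stood at 42.9% ± 3.89 (SD, n = 4) and 28.6% ± 9.18 (SD, n = 8; adjusted exact permutation p = 0.0848), with GAD2, an enzyme of GABA synthesis, marked in 3 KRAB, 0 ZNF-G1 and 2 ZNF-G2 libraries. Neural progenitor genes stood at 58.3% and 43.8% (adjusted exact permutation p = 0.206). CDH2, a cadherin of neural cells, was marked in 4 KRAB, 0 ZNF-G1 and 4 ZNF-G2 libraries. Chromatin regulators of neurodevelopmental disorders stood at 82.4% and 74.6% (adjusted exact permutation p = 0.262), with 12 of 34, among them ARID1A, ADNP and CHD8, marked in all 12 libraries. CTCF and cohesin genes stood at 91.1% and 76.8%, cell cycle genes at 86.0% and 69.5% (adjusted exact permutation p = 0.0848 for each) and ribosomal protein genes at 86.0% and 67.5% (adjusted exact permutation p = 0.0970). Of markers of other cell types, dorsal telencephalic genes stood at 37.5% and 28.9%, posterior neural genes at 15.8% and 10.5% and pluripotency genes at 35.4% and 23.96% (adjusted exact permutation p = 0.262, 0.268 and 0.152). Non-neural lineage genes had an adjusted exact permutation p of 0.782.

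**Figure D2:**
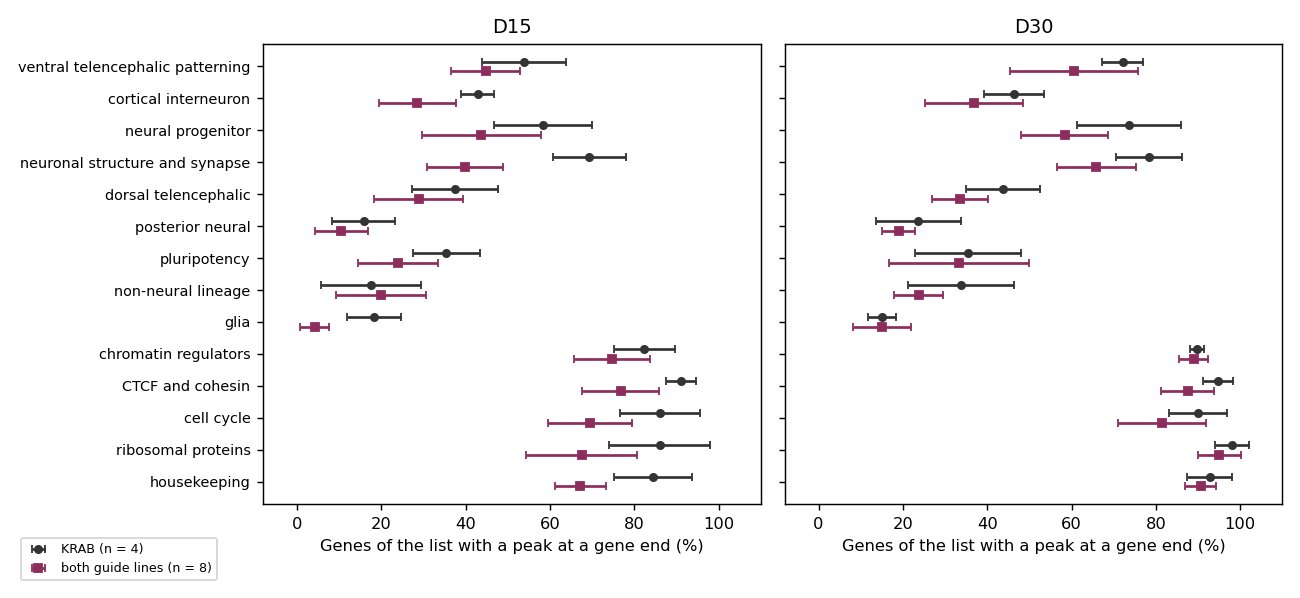
Percent of the genes of each of 14 fixed lists with a peak within 1000 bp of a gene end (horizontal axis), at D15 (left) and D30 (right). Points are means and bars SDs over 4 KRAB libraries (circles) and 8 guide libraries (squares); at D15 the neuronal structure and synapse list stood at 69.3% in KRAB and 39.8% in the guide libraries.

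Per gene, Fisher's exact test called 0 genes at D15 over the 5605 tested, where the smallest adjusted p was 0.132. At an unadjusted p under 0.05, 414 genes were lower in the guide libraries and 1 was higher. Adjusted over the list alone, 1 posterior neural gene and 1 glial gene passed. They were GBX2, a factor of the midbrain and hindbrain boundary, marked in 4 of 4 KRAB and 0 of 8 guide libraries (adjusted over the list alone, Fisher's exact p = 0.00404), and S100B (p = 0.0202). That adjustment covered only the few members whose total presence allows p under 0.05, and no other list. Adjusted over all genes tested, Fisher's exact p was 0.132 and 0.201, so neither passed. At D30 GBX2 was marked in 4 KRAB, 3 ZNF-G1 and 3 ZNF-G2 libraries, and S100B in 4, 2 and 3. In all, 86 genes had a peak in 4 of 4 KRAB and 0 of 8 guide libraries, and 0 had the opposite. Besides ZNF292 and LOC124901355, which lies next to it and shares the peak, those with the highest-ranked peaks were RHOJ, a small GTPase, VXN, a regulator of neurogenesis, TGFBR1, a receptor of TGF-beta, VEPH1, and PCDHGA1, PCDHGA10, PCDHGA11 and PCDHGA12. These protocadherin genes, cell adhesion molecules of neurons, share their end on chromosome 5 at 141512975 and rest on the same peak. Each is still counted by itself among the 414 and the 86 genes, which therefore hold more genes than separate sites. RHOJ lies on chromosome 14 from 63204443 to 63293508, VXN on chromosome 8 from 66493566 to 66518524 and TGFBR1 on chromosome 9 from 99103647 to 99154192. In the other direction HMX1, a homeobox gene chosen after its values were seen, was marked in 0 of 4 KRAB and 7 of 8 guide libraries (Fisher's exact p = 0.0101, adjusted 0.201).

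Per region, the 12 D15 libraries gave 237614 merged regions, of which 2881 were shared by all 12 libraries and 194881 were found in 1. Of 18491 regions tested, 1617 fell and 1 rose in the guide libraries at a Benjamini-Hochberg adjusted Fisher's exact p of 0.0231. Each of the 1617 had a peak in 4 of 4 KRAB and 0 of 8 guide libraries. Of the regions lost at D15, 7.05% were at a gene end, 47.3% elsewhere inside a gene and 45.6% outside genes. Among 2844 regions also found in exactly 4 libraries but not called, 23.9% were at a gene end (odds ratio 0.241, Fisher's exact p = 1.1e-50 over regions, which are not independent replicates). The regions not called were by definition never in all KRAB libraries and always in a guide library. Odds ratios against them therefore also hold how the KRAB and guide lists differ, whatever was lost. Regions shared by all 12 libraries were at a gene end in 80.2% of cases, and 67.1% of them overlapped an IgG peak of the day, against 7.92% of the regions lost and 10.3% of the regions in exactly 4 libraries that were not called (odds ratio 0.746, Fisher's exact p = 0.00778 over regions). Those with the highest-ranked peaks lay on chromosome 6 from 18022541 to 18023455, 34905 bp from KIF13A, on chromosome 1 from 15042695 to 15043416 inside KAZN, on chromosome 7 from 151538855 to 151539693, 16433 bp from PRKAG2, on chromosome 20 from 18224795 to 18225694, 36759 bp from KAT14, and on chromosome 21 from 16588098 to 16588804, whose nearest gene is USP25. The adjusted p of the region that rose rests on the lower regions that share its p. It lay on chromosome 1 from 6962367 to 6963277, inside CAMTA1, a transcription activator of neurons. With the libraries thinned to 1 depth, 0 regions passed (smallest adjusted Fisher's exact p = 0.0619), while 2022 were lower and 7 higher at an unadjusted p under 0.05. Without KRAB replicate 1, 3478 regions were called lower, in lists of equal length 831, and with presence set by peaks that cover 50% of the region 5504. With no filter on total presence, so that all 237614 regions entered the adjustment, 0 passed. Tested within replicate numbers, where the smallest possible exact p is 0.0123, 0 regions passed as well.

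**Figure D3:**
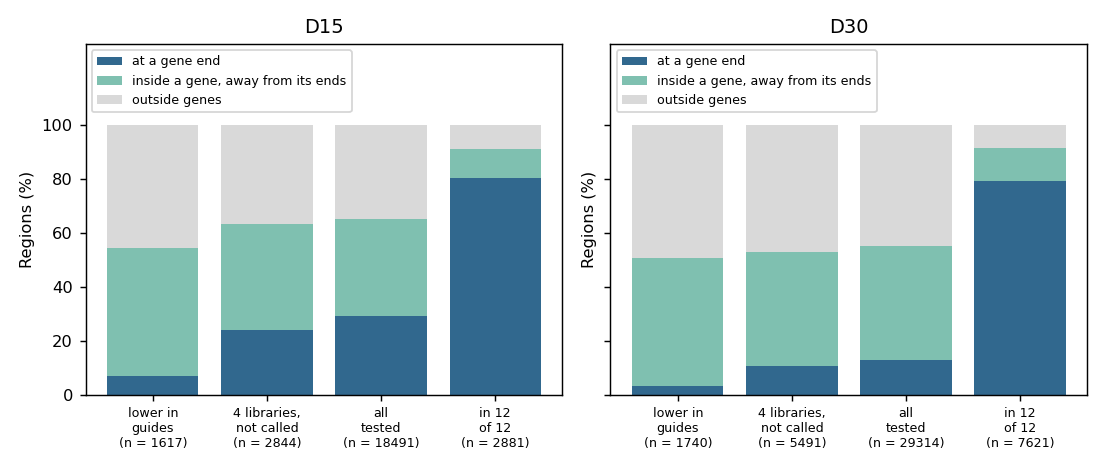
Share of regions (vertical axis, percent) at a gene end, elsewhere inside a gene or outside genes, for regions called lower in the guide libraries, regions found in 4 of the 12 libraries but not called, all tested regions and regions found in all 12 libraries, at D15 (left) and D30 (right). Of the regions called lower, 7.05% at D15 and 3.16% at D30 were at a gene end.

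Each guide was also compared with KRAB by itself at D15. Regions with a peak in 4 of 4 KRAB and 0 of 4 guide libraries numbered 2759 for ZNF-G1 and 2256 for ZNF-G2, and the opposite numbered 6 and 10. Both guides shared 1617 of them. With the same KRAB libraries on both sides, simulated guide lines with unchanged presence rates lost 64.05 regions each on average and shared 8.15, lists too short to be set against the overlap seen. Independent lists of these lengths would share 26.2 among the 237614 regions, or 477 among the 13061 regions present in 4 of 4 KRAB libraries. With the KRAB libraries split into pairs, 1 pair for each guide, the shared regions were the same 1617 by the rule's construction, and independent lists would share 112. The excess is not taken as a shared effect, since part of it may come from the shared controls. The losses were 5345 and 4563 without KRAB replicate 1, 1321 and 1271 in lists of equal length, and 645 and 673 after thinning to 1 depth. In number of peaks, ZNF-G1 averaged 25005 ± 1279 (SD, n = 4; log2 ratio to KRAB -0.83, exact permutation p = 0.0286, adjusted 0.0762) and ZNF-G2 33451 ± 11583 (SD, n = 4; log2 ratio -0.41, exact permutation p = 0.143). The guides together averaged 29228 ± 8865 (SD, n = 8) against 44437 ± 5341 (SD, n = 4) in KRAB, a log2 ratio of -0.60 (exact permutation p = 0.0141, adjusted over 8 comparisons 0.0762). The guides were not shown to differ from each other (ratio of ZNF-G2 to ZNF-G1 1.34, exact permutation p = 0.171). After thinning to 1 depth the log2 ratio of both guides to KRAB was -0.34 (exact permutation p = 0.352). Without ZNF-G2 replicate 2 the ratio of ZNF-G2 was -0.66 (exact permutation p = 0.0286).

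**Figure D4:**
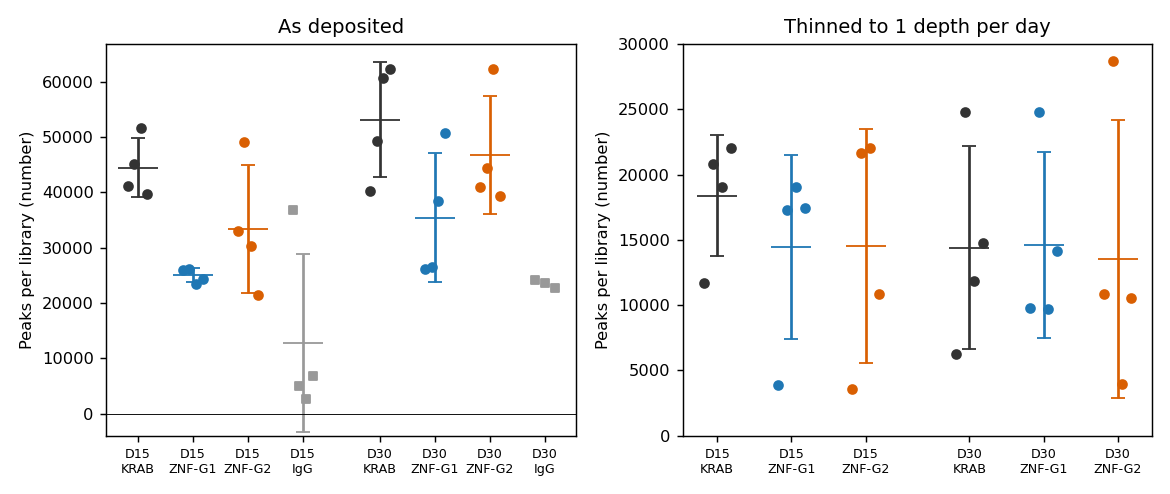
Number of peaks per library (vertical axis) by day, line and antibody, as deposited (left) and for the ZNF292 libraries after thinning to the depth of the shallowest library of the day (right). Points are libraries, horizontal marks means and bars SDs over 4 libraries, and the D30 IgG points are 1 library labelled for each line; KRAB averaged 44437 peaks at D15 and 53141 at D30 as deposited.

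The same comparison was made in immature interneurons at D30. Across all genes the share with a peak at a gene end was 62.8% ± 3.79 (SD, n = 4) in KRAB and 57.0% ± 3.803 (SD, n = 8) in the guide libraries (exact permutation p = 0.0343). None of the 14 lists passed, with or without the share of all genes taken off. Neuronal structure and synapse genes stood at 78.4% ± 7.76 (SD, n = 4) and 65.9% ± 9.41 (SD, n = 8), and neural progenitor genes at 73.6% ± 12.3 (SD, n = 4) and 58.3% ± 10.3 (SD, n = 8; adjusted exact permutation p = 0.283 for each). ANK2 was marked in 4 KRAB, 2 ZNF-G1 and 1 ZNF-G2 libraries. Ventral telencephalic patterning genes stood at 72.1% and 60.6% and cortical interneuron genes at 46.4% and 36.9% (adjusted exact permutation p = 0.357 for each). DLX1, a homeobox factor of interneuron precursors, was marked in all 12 libraries, and LHX6, a factor of interneurons from the medial ganglionic eminence, in 4 KRAB, 3 ZNF-G1 and 1 ZNF-G2 libraries. SLC32A1, the vesicular GABA transporter, was marked in 4 KRAB, 2 ZNF-G1 and 0 ZNF-G2 libraries. Chromatin regulators stood at 89.7% and 89.0% (adjusted exact permutation p = 0.893), with 28 of 34 marked in all 12 libraries. Housekeeping genes stood at 92.7% and 90.6%, ribosomal protein genes at 98% and 95%, cell cycle genes at 90.0% and 81.5% and CTCF and cohesin genes at 94.6% and 87.5% (adjusted exact permutation p = 0.710, 0.634, 0.357 and 0.283). Glial genes stood at 15% in both, dorsal telencephalic genes at 43.8% and 33.6%, posterior neural genes at 23.7% and 19.1%, pluripotency genes at 35.4% and 33.3% and non-neural lineage genes at 33.8% and 23.8% (adjusted exact permutation p = 1.00, 0.283, 0.528, 0.912 and 0.283). After thinning to 1 depth the share over all genes was 34.6% in KRAB and 33.9% in the guide libraries (exact permutation p = 0.935).

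Per gene, Fisher's exact test called 0 of 3149 genes at D30 (smallest adjusted p 0.163), with 139 lower and 5 higher at an unadjusted p under 0.05, and 0 when adjusted over the list alone. A peak in 4 of 4 KRAB and 0 of 8 guide libraries was found at 37 genes. Those with the highest-ranked peaks included LRRTM2, a postsynaptic adhesion molecule, SGIP1, an endocytic protein of neurons, LASP1NB, SORBS2, a cytoskeletal adaptor, EPCIP, BCHE, butyrylcholinesterase, MGST2, CA12, a carbonic anhydrase, and ADTRP (Fisher's exact p = 0.00202, adjusted 0.163). LRRTM2 lies on chromosome 5 from 138868921 to 138875335, SGIP1 on chromosome 1 from 66533361 to 66751139 and BCHE on chromosome 3 from 165772904 to 165837423. The opposite, 0 of 4 KRAB and 8 of 8 guide libraries, was found at 2 genes, PNPLA4 and TESMIN, named after their values were seen. Of the genes with a peak in every KRAB and no guide library, 6 were found at both days: CSRNP3, BCHE, MGST2, HSPB3, LRRTM2 and MID1. Independent lists would share 0.219. Both lists require a peak in every KRAB library, so the excess also holds what KRAB libraries share between days, whatever the guides did.

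Per region, 1740 of 29314 regions tested at D30 fell and 5 rose in the guide libraries (adjusted Fisher's exact p = 0.0339). All 1740 had a peak in 4 of 4 KRAB and 0 of 8 guide libraries, and 7621 regions were shared by all 12. As at D15, the other regions found in 4 libraries were never in all KRAB libraries, which limits the odds ratio against them. Of the regions lost, 3.16% were at a gene end, 47.6% elsewhere inside a gene and 49.2% outside genes, while 10.5% of the 5491 other regions found in 4 libraries were at a gene end (odds ratio 0.279, Fisher's exact p = 4.2e-25 over regions). Those with the highest-ranked peaks lay on chromosome 13 from 109494623 to 109495336, with IRS2 as the nearest gene, on chromosome 21 from 37435181 to 37435604 inside DYRK1A, a kinase gene of neurodevelopment, on chromosome 2 from 1010431 to 1010973 inside SNTG2, on chromosome 5 from 116777971 to 116778519, nearest to SEMA6A, an axon guidance protein, and on chromosome 2 from 223688327 to 223688918, nearest to AP1S3. The adjusted p of the 5 that rose rests on the lower regions that share their p. They lay inside RAP1GAP (chromosome 1, 21607754 to 21608224), CAMTA1 (chromosome 1, 6962409 to 6963413) and SYNGR3 (chromosome 16, 1991887 to 1992606) and across an end of PNPLA4 (chromosome X, 7926955 to 7928012) and TESMIN (chromosome 11, 68751022 to 68751955). After thinning to 1 depth 0 regions passed, and 674 were lower and 17 higher at an unadjusted Fisher's exact p under 0.05. In lists of equal length 846 were called lower, and with no filter on total presence 0. Tested within replicate numbers, where the smallest possible exact p is 0.0123, 0 regions passed. Leaving out KRAB replicate 2, 3 or 4 or ZNF-G1 replicate 1 left 0 regions called, and leaving out KRAB replicate 1 gave 3278. Counted without adjustment, those with 0 calls held 2404, 2004, 2223 and 1824 regions, so the 0 arises at the adjustment.

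Taken by itself at D30, ZNF-G1 lacked 3333 and ZNF-G2 3123 of the regions present in 4 of 4 KRAB libraries, and the opposite numbered 23 and 93. Both guides shared 1740, where simulated unchanged lines lost 92.03 each and shared 11.75 on average, and independent lists would share 41.3, or 525 among the 19809 regions present in 4 of 4 KRAB libraries, or 185 with the KRAB libraries split into pairs. As at D15, the excess is not taken as a shared effect. The losses were 5678 and 5874 without KRAB replicate 1, 1562 and 1741 in lists of equal length, and 183 and 241 after thinning. The guide libraries averaged 41104 ± 11972 peaks (SD, n = 8) against 53141 ± 10373 (SD, n = 4) in KRAB, a log2 ratio of -0.37 (exact permutation p = 0.125). ZNF-G1 averaged 35440 ± 11648 (SD, n = 4; log2 ratio -0.58, exact permutation p = 0.0857) and ZNF-G2 46767 ± 10640 (SD, n = 4; log2 ratio -0.18, exact permutation p = 0.429). The effect of the guides on peak number was not shown to differ between days (difference of log2 ratios 0.23, permutation p = 0.466). After thinning the log2 ratio of the guides was -0.03 (exact permutation p = 0.935), and without ZNF-G2 replicate 3 it was -0.48 (exact permutation p = 0.0455).

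A further question was whether peaks at gene ends made up a different part of the lists. They made up 25.5% of peaks in KRAB and 28.9% in the guide libraries at D15, a difference of 3.36 points (exact permutation p = 0.360). At D30 the difference was 5.04 points (exact permutation p = 0.182). In lists of equal length the sign turned at both days, to -6.05 points at D15 (exact permutation p = 0.0768) and -0.92 at D30 (exact permutation p = 0.503).

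The last comparison followed the control line from progenitors to immature interneurons. Of 183746 regions found in the 8 KRAB libraries, 11193 were present in all of them, 1700 in 4 of 4 D30 and 0 of 4 D15 libraries, and 189 in 4 of 4 D15 and 0 of 4 D30 libraries. Without D15 KRAB replicate 1 the D15 count was 816, without D15 KRAB replicate 2 it was 291, and in lists of equal length 297. Without D30 KRAB replicate 1 the D30 count was 3551, and without D30 KRAB replicate 2 it was 2579. Gene ends with a peak in all D30 and no D15 libraries numbered 93, and the opposite numbered 5, although Fisher's exact test called 0 of 621 genes tested (smallest adjusted p 0.181, unadjusted p 0.0286 for each of these genes). Among the fixed lists the D30 genes were SLC32A1, ELAVL3, an RNA-binding protein of neurons, BCL11B, a factor of deep-layer projection neurons, and SLC1A2, a glutamate transporter. The 5 D15 genes, named after their values were seen, were FEZF2, a dorsal forebrain factor, HIC1, AQP2, TSGA10IP and WFIKKN1. Ventral telencephalic patterning genes stood at 53.8% ± 9.93 (SD, n = 4) at D15 and 72.1% ± 4.84 (SD, n = 4) at D30 (exact permutation p = 0.0571, adjusted 0.480), and none of the 14 lists passed with or without the share of all genes taken off. Peaks averaged 44437 ± 5341 (SD, n = 4) at D15 and 53141 ± 10373 (SD, n = 4) at D30, a log2 ratio of 0.26 (exact permutation p = 0.229). After thinning the 8 libraries to 1 depth the log2 ratio was -0.61 (exact permutation p = 0.114), with 109 regions found in every D30 and no D15 library and 471 in the opposite direction. Thinning left fewer peaks in the libraries with a higher background (Spearman correlation -0.905, n = 8, exact permutation p = 0.00456), so these values do not show what depth did.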

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

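All tests of the patterns below were set before their results were seen, except that the leave-one-out range for lists of equal length was added after the D15 value was known, and thinning itself and its relation to the background were chosen after seeing the data. Among 27 groups and measures tested for a library far from the others, 2 stood out, and chance gives about 1 in 20. The D15 KRAB IgG replicate 1 held 36815 peaks, where the nearest of the other 3 libraries held 6733. The D15 ZNF-G1 replicate 1 had a genome background of 0.380, where the nearest of the other 3 had 0.124.

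Fewer peaks were listed in the guide libraries at D15, with a ratio of means of 0.658. After thinning to 1 depth the ratio was 0.788 (exact permutation p = 0.352), so a difference in depth cannot be told apart from fewer sites. Thinning left the difference within the spread of the libraries, and the thinned number itself fell with the background (Spearman correlation -0.622, n = 12, permutation p = 0.0349). An even drop of signal over background at all sites may also shorten a list, and lists of equal length would then lose few regions. In such lists 51.391% as many regions were called lower, and with 1 library left out, counted without adjustment, 47.4% to 55.2%. After adjustment, lists of equal length called 0 regions without KRAB replicate 2, 3 or 4, where the smallest possible p is higher. The lists as deposited then still called 2025, 1727 and 1977. Under 10% was set beforehand as the mark of an even drop and at least 50% as the mark against it. The value with all libraries and the unadjusted ones lie far above the former, and the first passes the latter by less than their spread. The adjusted counts of 0 lie below the former. That explanation therefore stays open. A loss of binding in the guide lines stays open as well.

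At D30 the ratio of peak numbers was 0.773 and after thinning 0.977, but the thinned number fell with the background (Spearman correlation -0.692, n = 12, permutation p = 0.0151). The library with the highest background, 1.04, kept 3974 peaks and that with the lowest, 0.120, kept 24810. A ratio near 1 is then favoured whatever the cause, and a difference in depth cannot be told apart from fewer sites. Lists of equal length gave 48.621% as many regions called lower, and 38.96% to 51.7% with 1 library left out, counted without adjustment. After adjustment, lists of equal length kept calls with 1 library left out only without ZNF-G2 replicate 4, with 1031 regions, and otherwise called 0. The value with all libraries and the unadjusted ones are far above 10% and lie on both sides of 50%. The adjusted counts with 1 library left out mostly fall to 0. An even drop is therefore left open.

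KRAB libraries held more peaks at D30 than at D15, with a ratio of 1.196. After thinning the ratio was 0.656, but the thinned number fell with the background in these 8 libraries as well (Spearman correlation -0.905, exact permutation p = 0.00456). The deeper day is lowered by this whatever the cause, so a difference in depth cannot be told apart from a change in the number of sites. No biological explanation of the day was tested apart from depth.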

How the results depend on the processing

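Thinning, whole gene spans and leaving out the D15 libraries numbered 1 were tests chosen only after the data were seen. Over all alternatives, 387 results kept direction and side of the threshold or stayed within 1.5 times. Another 67 moved, 12 were weaker, 3 stronger and 7 reversed. The 387 include counts that stayed at 0 and tests that passed in neither setting, so they do not measure how firm the calls are. Where no cause is given, the cause was not tested. Depth limits all counts, since a shallow library misses weak sites.

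After thinning to 1 depth the log2 peak-number ratio was -0.34 for both guides at D15 (exact permutation p = 0.352), -0.35 for ZNF-G1 (0.457), -1.26 for IgG (0.0857), 0.021 for ZNF-G1 at D30, reversed, and -0.61 for KRAB D30 over D15, reversed. Regions called lower and higher were 0 and 0 at D15 and 0 and 0 at D30. Regions lost were 645 in ZNF-G1 and 673 in ZNF-G2 at D15, and 183 and 241 at D30. The share of peaks at gene ends differed by -0.371 at D15, reversed, neuronal structure and synapse passed relative to all genes at D15, and KRAB regions numbered 471 for D15 only and 109 for D30 only.

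Correlations of same-numbered libraries were small, 0.00242 to 0.128 at D15 (1 of 12 pairs over 0.1) and -0.0109 to 0.0477 at D30 (0 of 12). At D15 12 of 12 libraries correlated best with their own number. The median there was 0.0221 for same and -0.00579 for different numbers. The D15 libraries of a number thus resembled each other slightly, so testing within replicate numbers bears on the D15 calls. At D30 5 of 12 libraries correlated best with their own number (medians 0.0110 and -0.00290), so pairing was not shown there. With the replicate block ZNF-G1 at D15 kept -0.83 (exact permutation p = 0.125) and IgG -1.79 (p = 0.125), the smallest that block allows, and regions lower and higher were 0 and 0 at both days (smallest adjusted p 0.0642 and 0.0885). Thinning with the replicate block gave -0.34 for both guides at D15 (exact permutation p = 0.123), -0.35 for ZNF-G1 (0.25) and 0.021 for ZNF-G1 at D30, reversed.

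With a stricter threshold the D30 guides stood at -0.54 (exact permutation p = 0.0263), 2 gene lists relative to all genes passed at D15, neuronal structure and synapse and non-neural lineage, and 3 regions were higher at D30. Without IgG peaks, 2 were higher at D15. In lists of equal length, regions lower and higher were 831 and 5 at D15 and 846 and 10 at D30, regions lost 1321 and 1271 at D15 and 1562 and 1741 at D30, the gene-end share differed by -6.05 at D15 and -0.917 at D30, both reversed, non-neural lineage passed relative to all genes at D15, and 297 regions were D15 only. Summit windows gave 3 regions higher at D15. An overlap of 50% gave 5504 lower and 3 higher at D15 and 1 higher at D30. A 2500 bp window passed glial genes relative to all genes at D15, and gene spans turned the D15 share to -0.920. With no filter 0 and 0 regions passed at both days, because more regions enter the adjustment. Without the D15 libraries numbered 1, ZNF-G1 stood at -0.88 (exact permutation p = 0.1, the smallest 3 against 3 allows), 3736 regions were lower and 4 higher, and 5654 and 4909 were lost.

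Leaving out each library in turn gave log2 ratios of -0.75 to -0.52 for both guides at D15, -0.88 to -0.75 for ZNF-G1 at D15, -0.66 to -0.25 for ZNF-G2 at D15, -0.48 to -0.28 for both guides at D30, -0.81 to -0.46 for ZNF-G1 at D30, -0.35 to -0.10 for ZNF-G2 at D30, 0.17 to 0.37 for KRAB between days, -3.20 to -1.46 for IgG, 0.12 to 0.38 for the difference between days. Regions ranged over 1671 to 3478 lower at D15, 1 to 2 higher at D15, 2897 to 5345 lost in ZNF-G1 at D15, 2402 to 4563 lost in ZNF-G2 at D15, 0 to 3278 lower at D30, 0 to 8 higher at D30, 3646 to 5678 lost in ZNF-G1 at D30, 3389 to 5874 lost in ZNF-G2 at D30, 218 to 816 D15 only, 1946 to 3551 D30 only. The gene-end share ranged over 1.93 to 4.72 points at D15 and 3.44 to 6.33 points at D30, and gene ends and lists relative to all genes stayed at 0. The highest counts of regions lower and lost came without KRAB replicate 1 of the day. At D30, 0 regions lower came without KRAB replicate 2, 3 or 4 or ZNF-G1 replicate 1, where the unadjusted counts were 2404, 2004, 2223 and 1824. ZNF-G2 at D15 passed without ZNF-G2 replicate 2 (-0.66, exact permutation p = 0.0286) and both guides at D30 without ZNF-G2 replicate 3 (-0.48, exact permutation p = 0.0455). IgG did not pass without any 1 of the KRAB ZNF292 libraries (exact permutation p = 0.0571).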

Other observations

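The overlap of days and its splits, the splits of regions in 4 and 0 of 8 libraries as deposited, and the counts of regions within genes, widths and chromosome shares, were tests chosen only after the data were seen. Of the 1617 regions lower at D15, 230 (14.2%) overlapped a region lower at D30, against 60 of 2844 (2.11%) regions found in 4 libraries and not called (odds ratio 7.69, Fisher's exact p = 2.6e-54 over regions, which are not independent replicates). The regions not called were by definition never in all KRAB libraries of D15, and a region lower at D30 had to be in all KRAB libraries of D30. The odds ratio therefore also holds what KRAB libraries share between days, whatever the guides did. The highest-ranked of the 230 lay on chromosome 1 from 15042695 to 15043416 in KAZN, on chromosome 10 from 113273120 to 113274241 outside genes and on chromosome 8 from 119657507 to 119658324 in ENPP2. Next came those on chromosome 15 from 70701809 to 70702452 in UACA and on chromosome 7 from 78139356 to 78139731 in MAGI2. Of 100 splits that moved libraries of the same line and number together at both days, 1, the real one, gave 230, and the highest other gave 1. The longest D15 list of the other splits held 183 regions, so none of them was able to reach 230, and this comparison cannot tell whether the overlap arose by chance. The region inside CAMTA1 was higher in the guide libraries at both days.

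Peaks were narrower on average in the guide libraries. The median width was 294 bp in KRAB and 247 bp in the guide libraries at D15, which did not pass (adjusted exact permutation p = 0.0566). At D30 it was 292 and 242 bp (adjusted exact permutation p = 0.0388). The mean width was 357 ± 42.3 bp (SD, n = 4) in KRAB and 286 ± 22.05 bp (SD, n = 8) in the guide libraries at D15 (adjusted exact permutation p = 0.0242 over 12 tests). At D30 it was 376 ± 16.6 and 317 ± 31.3 bp (n = 4 and 8, adjusted exact permutation p = 0.0388). Peaks covered 16.03 Mb in KRAB and 8.33 Mb in the guide libraries at D15 (adjusted exact permutation p = 0.0242), and 20.04 and 12.9 Mb at D30 (adjusted exact permutation p = 0.0388). None of 46 chromosome shares passed (smallest adjusted exact permutation p = 0.0929). Among genes with at least 2 lower regions in their span, 0 of 126 at D15 and 0 of 110 at D30 passed (smallest adjusted p 0.213 and 0.141), with 5 regions each in MAGI1, NTRK2 and PTPRM at D30.

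In 100 splits of the 12 libraries of a day into 4 and 8, 1, the real one, gave as many regions lower after adjustment (D15 1617, D30 1740), and the highest other gave 0. This 0 says little, since a call needs many regions at the smallest p. Counted without adjustment, as regions in 4 of 4 and 0 of 8 libraries, 1 of 100 splits, the real one, gave as many. These were 1617 at D15 against at most 125 in the others, and 1740 at D30 against at most 183. A chance split is therefore unlikely, at 1 in 100, but not excluded, since the splits drawn did not respect replicate numbers. At D30 the adjusted count falls to 0 without KRAB replicate 2, 3 or 4 or ZNF-G1 replicate 1. Counted without adjustment these settings gave 2404, 2004, 2223 and 1824 regions, so the 0 arises at the adjustment, where fewer libraries raise the smallest possible p. For the regions higher (D15 1, D30 5), 1 of 100 splits gave as many too, but their adjusted p rests on the lower regions that share their p, so this comparison cannot tell whether they arose by chance. For gene ends all 100 splits gave 0, as the real one did. For each guide by itself, 1 of 35 splits gave as many regions in 4 and 0 libraries: 2759 and 2256 at D15 against at most 324 and 379, and 3333 and 3123 at D30 against at most 515 and 455. After thinning, 1 of 100 splits gave as many regions in 4 of 4 and 0 of 8 libraries, 412 at D15 against at most 104, and 104 at D30 against at most 84. The highest others were KRAB replicates 2, 3 and 4 with ZNF-G1 replicate 3 at D15 and with ZNF-G1 replicate 2 at D30. Between days in KRAB, 1 of 35 splits gave the 1700 regions found at D30 alone, the highest other 611. At least the 189 regions found at D15 alone were given by 6 of 35 splits, the highest 611, so chance is not excluded for those 189.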
